A study of Mus musculus with 20 samples.

How the data were processed

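DNA came from 20 libraries of microglia-enriched brain homogenate of B6D2F1/J background mice, which descend from a cross of the C57BL/6J and DBA/2J strains. The deposited files hold, for each library, the percent methylation at each CpG, and per the submitters' processing notes Bowtie2 and methylKit were used with the mm10 build, with no versions given. The files give no read counts, so the read depth is unknown and no interval that needs it is given. Within an age every library listed the same CpGs, 1151247 at 13 months and 1234494 at 3 months, of which 1132618 were shared. Adjacent positions, as the 2 strands of a CpG are, were listed apart, and each is counted here as a CpG unless strands were averaged. A table of all 13-month libraries had 13 value columns, of which 1 equalled no library's file and was not used. No library duplicated another: mean absolute differences between libraries of an age ran from 3.39 to 5.09 points.

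The tests fixed before the data were examined needed methylated and unmethylated read counts. Since the files hold percentages, CpGs were instead tested with limma 3.58.1 in R 4.3.3 on log2((percent + 1) / (100 - percent + 1)), with moderated variances and Benjamini-Hochberg adjustment. Features on chromosomes 1 to 19, X and Y with a mean of 5% to 95% over the libraries compared were tested. Calls needed an adjusted p under 0.05 and a difference in group mean percent of at least 10 points for CpGs or 5 points for tiles and gene regions, and interactions an adjusted p under 0.05. The gene table, of the same assembly as mm10, has no strand, so promoters could not be placed, and non-overlapping 1000 bp tiles with at least 3 CpGs took their place. Gene regions were annotated genes with 1000 bp either side and at least 3 CpGs. Groups came from the labels. Global means, list means and single-locus values were compared with two-sided exact permutation tests. The labels do not state sex, and the series' design text calls the samples mice. Every library had values at CpGs of the Y chromosome, 866 at 13 months and 945 at 3 months, and sex was not tested. Alternatives covered the scale, the offset, the mean filter, the variance model, the minimum difference, tile size, gene parts, strands, chromosomes, a covariate, a replicate block and each library left out.

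Named loci followed a rule written before the data were examined for promoters, here applied to tiles. It took the 10 of largest difference in each direction among the calls of a genotype comparison, and with fewer than 10 calls also the 5 of smallest p in each direction. It also took the 5 called CpGs of largest difference in each direction, called members of the 18 gene lists, the 2 members of smallest p of each list, and Thy1. For age and the interaction it took the 5 called promoters of largest difference in each direction. CpGs named between ages, the CpG of the interaction and CpGs named at 3 months fall outside that rule and were chosen after their values were seen. All 318 listed symbols were in the gene table. The planned check of the labels by read coverage of Thy1 was not run, and its methylation was examined after the data were seen.

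The method was tested on simulated data built from the observed means and spreads, with 200 changed features of each size. Changes were placed only in features of intermediate mean methylation. The rates therefore do not cover CpGs near the limits of the scale, where the CpGs called at 13 months lay. At 13 months 0% of single-CpG changes of 20 points, 28.5% of 40 points and 51.0% of 60 points were recovered among 453891 CpGs, and at 3 months 0%, 1% and 21% among 492274. For tiles, changes of 10 points were recovered in 4.5% at 13 months and 0% at 3 months, of 20 points in 35.5% at 13 months and 38.0% at 3 months, and of 40 points in 81.5% and 83.0%. Mean estimated differences for simulated CpG changes of 60 points were 57.5 points at 13 months and 58.3 points at 3 months. Among unchanged features 3 CpGs and 9 tiles were called at 13 months, and 4 CpGs and 11 tiles at 3 months. Counts of 0 therefore leave room for undetected differences.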

Results

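Methylation of cytosines in CpG pairs was measured by reduced representation bisulfite sequencing, which reads the CpG-rich part of the genome after an enzyme digest, in DNA from mouse brain homogenate enriched for microglia, the resident immune cells of the brain. HEM mice overexpressed human wild-type α-synuclein, the protein that aggregates in Parkinson disease, under the Thy-1 promoter from a transgene on the X chromosome, and WT mice were controls. There were 8 HEM and 4 WT libraries at 13 months and 4 HEM and 4 WT libraries at 3 months. The series' own design text counts 3 WT mice at 3 months, and all 4 libraries labelled so were used. The values were percent methylation at 1151247 CpGs at 13 months and 1234494 CpGs at 3 months, and the read depth behind each percentage is unknown.

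Mean methylation did not separate HEM from WT at either age. At 13 months the mean over all CpGs of chromosomes 1 to 19, X and Y was 31.0% ± 0.872 (SD, n = 8) in HEM and 31.0% ± 0.344 (SD, n = 4) in WT, and the two-sided exact permutation p was 0.990. At 3 months it was 31.6% ± 0.160 (SD, n = 4) in HEM and 31.6% ± 0.445 (SD, n = 4) in WT, with an exact permutation p of 0.914. The smallest p that these designs can give is 0.00202 at 13 months and 0.0286 at 3 months. CpGs within 1 kb of an annotated gene end, CpGs inside genes, CpGs outside coding genes and CpGs of X also showed no difference that passed the test at either age. Methylation of microglia marker gene regions varied more, from 39.9% to 58.5% across libraries, with no genotype difference past the test.

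**Figure D1:**
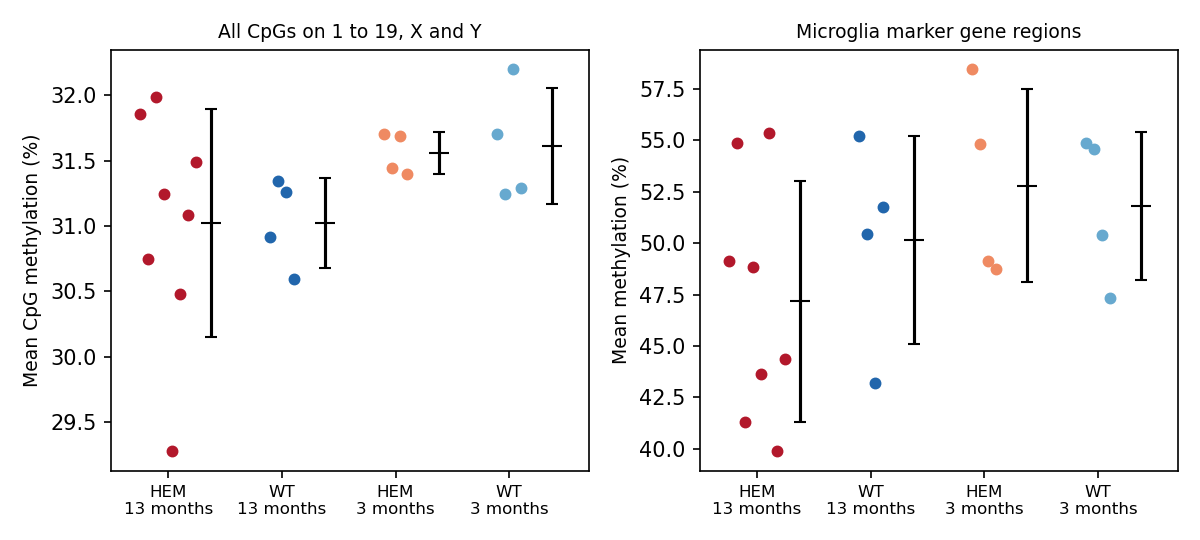
Mean methylation in percent of each library (points) over all CpGs, left, and over microglia marker gene regions, right, for the 4 groups, with the group mean and SD as bars; neither axis starts at 0. Marker region means ran from 39.9% to 55.3% within HEM at 13 months.

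The first comparison asked which loci differed between α-synuclein mice and controls at 13 months. Of 453891 CpGs tested, 4 were called, 1 higher and 3 lower in HEM. A CpG at position 146932654 of chromosome 4 (mm10), inside the zinc finger gene Zfp993, was at 13.3% ± 4.58 (SD, n = 8) in HEM and at 0% in all 4 WT libraries (limma adjusted p = 0.00216). A CpG at 18972397 of chromosome 13, inside Amph, which encodes the synaptic vesicle recycling protein amphiphysin, was at 86.6% ± 3.74 (SD, n = 8) in HEM and at 100% in every WT library (limma adjusted p = 0.00135). A CpG at 58006609 of chromosome 11 in Larp1, an RNA-binding regulator of translation, was at 87.1% ± 5.94 in HEM and 100% in WT (limma adjusted p = 0.0125). The last lay at 56526372 of X, 17500 bp from Gm648, at 89.6% ± 4.40 in HEM and 100% in WT (limma adjusted p = 0.0125). In all 4, and in all 14 CpGs with an adjusted p under 0.05 at any difference, every library of 1 group was at exactly 0% or 100%, where the log2 scale stretches small differences. On the percent scale the count was 0, and without WT replicate 1 it was 45.

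No 1 kb tile and no gene region was called at 13 months with limma. An unadjusted p under 0.05 was found for 3926 tiles (5.52% of those tested) and 462 gene regions (3.73%), where chance alone gives a share of about 0.05. Among the tiles with the smallest p, none of which passed, some overlapped Tiam1, Bcl2l1, Akap6 and Syt13 with higher values in HEM, by 7.45, 9.72, 7.10 and 16.3 points. Tiles with lower values in HEM overlapped Csmd1, Cgnl1 and Adamts17, with differences of -6.49, -11.9 and -6.26 points, or lay nearest Irx1 and Fgfr2, 113277 and 24192 bp away, at -7.95 and -5.99 points. Each of these had a limma adjusted p of 0.822.

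At 3 months the same question gave no called CpG, tile or gene region with limma. An unadjusted p under 0.05 was found for 22280 CpGs (4.53% of those tested), 3513 tiles (4.50%) and 494 gene regions (3.90%), shares below 0.05. CpGs inside Tcf7l1, a transcription factor of Wnt signalling, St6galnac3 and Dlgap1, a postsynaptic scaffold gene, were at 100% in all HEM libraries and at 83.1% ± 5.24, 86.8% ± 2.95 and 87.7% ± 2.48 (SD, n = 4) in WT. CpGs inside Cdk5, a neuronal kinase gene, and Celsr1 were at 83.4% ± 4.34 and 85.5% ± 3.05 in HEM and at 100% in all WT libraries. Each of these 5 had a limma adjusted p of 0.0503, was not called, and was named after its values were seen. The tile nearest to the threshold lay from 107085001 to 107086000 on chromosome 7, 10217 bp from the olfactory receptor gene Olfr714, at 73.7% ± 3.85 in HEM and 93.4% ± 1.21 in WT (SD, n = 4; limma adjusted p = 0.0864). Tiles in Col3a1 and Slc41a2 differed by 22.1 and -29.7 points with a limma adjusted p of 0.994. Without WT replicate 1 the CpG count at 3 months was 57.

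None of the 18 gene lists differed between HEM and WT at either age by exact permutation tests of list means, where the smallest adjusted p was 0.880 at 13 months and 0.643 at 3 months. At 13 months the microglia markers averaged 47.2% ± 5.86 (SD, n = 8) in HEM and 50.2% ± 5.04 (SD, n = 4) in WT, and 10 of 13 tested members had lower values in HEM. Among them P2ry12 and Cx3cr1, receptors of resting microglia, were at 65.5% and 80.5% in HEM and at 70.3% and 84.7% in WT, and Ms4a7 and Itgal, of other macrophages and leukocytes, differed by -5.45 and -3.54 points. At 3 months 11 of 14 microglia members had higher values in HEM, and the difference between the ages in this list was not tested. There Itgam and Irf8 differed by -1.82 and 3.37 points, and Pf4 and Mrc1 by 6.55 and 1.38 points. No member of any list was called over all genes, or adjusted over the list alone with the minimum difference of 5 points, at either age.

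For the markers of other cell types at 13 months, Snap25 and Rbfox3 of neurons differed by -0.738 and 1.83 points, Aldoc and Aqp4 of astrocytes by 1.43 and 6.004, Cldn11 and Pdgfra of the oligodendrocyte lineage by 1.49 and 0.806, and Cldn5 and Rgs5 of vessels by 1.30 and -5.63. At 3 months Th and Rbfox3 differed by -4.04 and -0.821 points, Aqp4 and Gja1 by -5.32 and 1.51, Mog and Mbp by -1.62 and -1.02, and Tek and Pecam1 by -4.06 and -1.66. Of the immune lists at 13 months, the disease-associated microglia genes Spp1 and Csf1 differed by -3.14 and 0.828 points, the cytokine genes Il10 and Tgfb1 by -8.73 and 1.63, Tlr9 and Nlrp3 of innate sensing by -2.31 and -3.15, and Tap1 and Irf9 of the interferon list by 1.51 and -2.23. At 3 months Spp1 and Timp2 differed by 8.61 and -0.976 points, Il6ra and Tnfrsf1b by 1.19 and 2.76, Tlr6 and Traf6 by 0.252 and -0.146, and Stat2 and H2-Eb1 by -3.68 and 5.51.

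In the Parkinson disease list at 13 months Dnajc6 and Tmem175 differed by 1.32 and 9.69 points, in the lysosome list Atp6v0d1 and Tfeb by 1.34 and 0.756, in the oxidative stress list Cat and Nfe2l2 by -1.33 and -1.98, and in the synaptic vesicle and dopamine list Snap25 and Nr4a2 by -0.738 and -2.07. At 3 months Fbxo7 and Tmem175 differed by -0.624 and -7.61 points, Becn1 and Atg7 by -0.653 and -1.27, Txn1 and Cat by -2.43 and 0.859, and Syn2 and Nr4a2 by -1.28 and 1.97. Among epigenetic and clustered genes at 13 months, Tet3 and Hells differed by 0.634 and 0.140 points, the imprinted genes Plagl1 and Dlk1 by -5.18 and 0.800, Hoxb3 and Hoxd3 by 2.45 and 0.933, and Pcdhgc3 and Pcdhgc5 by 1.24 and 4.01. At 3 months Uhrf1 and Tet2 differed by -0.578 and -0.586 points, Grb10 and Cdkn1c by 1.997 and 2.40, Hoxa5 and Hoxa3 by -3.07 and -1.77, and Pcdhga3 and Pcdhga1 by 1.93 and 1.90. Across the 210 and 213 listed genes tested at 13 and 3 months, the smallest limma adjusted p over all genes was 0.9996 and 0.9995.

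Thy1, whose promoter drives the transgene, was examined at each CpG. Thy1 lies from 44043384 to 44048579 on chromosome 9. At 4 CpGs past its annotated end, from 44049598 to 44049669, mean methylation at 3 months was 44.4% ± 6.76 (SD, n = 4) in HEM and 75.4% ± 24.4 (SD, n = 4) in WT, with an exact permutation p of 0.114. The library labelled WT replicate 3 at 3 months was at 38.9%, inside the HEM range of 37.4% to 52.6%, and the other WT libraries were at 83.9% or above. Without it the difference was -43.2 points (exact permutation p = 0.0286, the smallest possible). At 13 months HEM libraries spanned 31.8% to 89.8%, with a mean of 69.5% ± 20.7 (SD, n = 8), against 82.3% ± 2.58 (SD, n = 4) in WT (exact permutation p = 0.271). HEM replicates 3, 6, 7 and 10 were at 89.8%, 84.2%, 85.3% and 79.9%, within or above the WT range of 79.1% to 85.2% at that age. HEM replicates 1, 8, 11 and 13 were lower, at 74.5%, 31.8%, 46.4% and 63.7%. Labels were kept as given at both ages, and the size of the 3-month difference rests on the library labelled WT replicate 3. At single CpGs around Thy1 the smallest exact permutation p adjusted over the 27 CpGs was 0.109 at 13 months and 0.309 at 3 months.

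**Figure D2:**
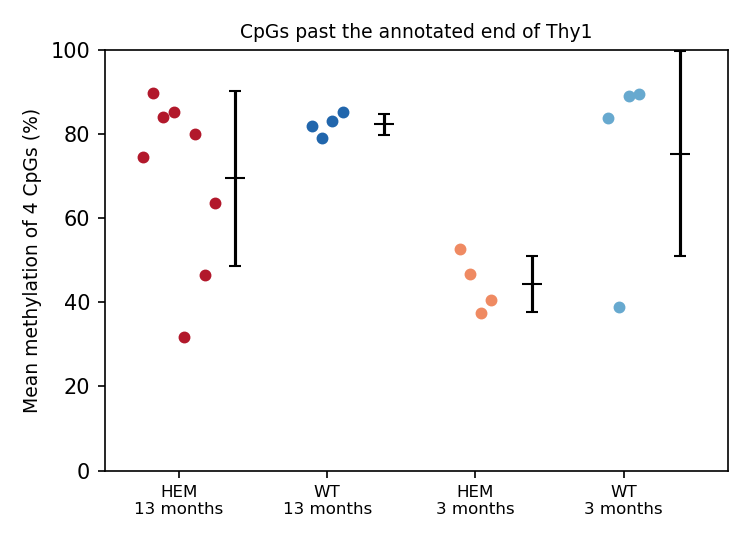
Mean methylation in percent of 4 CpGs past the annotated end of Thy1 in each library (points) of the 4 groups, with the group mean and SD as bars. One library labelled WT at 3 months was at 38.9%, and HEM libraries at 13 months ran from 31.8% to 89.8%.

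The comparison of 13 with 3 months called 81 of 442155 CpGs in WT, 74 of them higher at 13 months, and 136 of 445659 in HEM, 115 of them higher. The calls were concentrated in the genome: 55 of the 81 WT calls lay between 123923604 and 123933137 on chromosome 9, and 98 of the 136 HEM calls lay on chromosome 17. The coding gene nearest that stretch of chromosome 9 was the chemokine receptor gene Ccr1, 28988 bp or more away. Calls from 123925487 to 123925547 lay in the annotated gene Gm51701. The counts were 38 in WT and 20 in HEM on the percent scale and 14 and 8 without chromosomes 9 and 17, and 181 in WT without 13-month replicate 6. Age and the separately deposited sets of libraries coincide, so age and batch cannot be told apart in this comparison.

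The CpGs named between ages were chosen after their values were seen. In WT the CpGs with the widest increases, at 123924734, 123924699, 123924691, 123924712 and 123924719 of chromosome 9, were at 78.1% to 80.0% at 13 months and at most at 0.292% at 3 months. A CpG at 123933137 was lower, at 9.34% ± 6.78 against 94.9% ± 4.51 (SD, n = 4; limma adjusted p = 0.00601). Lower CpGs also lay in Mgmt, Ntpcr and Ehd3 and 18628 bp from Stk31, with differences of -16.8, -14.4, -11.2 and -15.2 points. Of 4 called tiles in WT, 3 lay in the same stretch, and the other, from 15433001 to 15434000 on chromosome 19, was lower at 13 months, at 82.0% ± 1.70 against 95.1% ± 0.782 (SD, n = 4; limma adjusted p = 0.0487).

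In HEM the widest increases were on chromosome 17, in Olfr91, Nudt3, Baiap3 and Treml1 and near Frs3, with 13-month means of 73.2%, 69.3%, 64.6%, 63.5% and 65.2% and 3-month means of at most 0.305%. Decreases lay in Lncpint and Prkce and nearest Psmb9, Olfr161 and Gpr149, with differences of -41.6, -26.1, -36.9, -36.2 and -24.1 points. Psmb9, Olfr161 and Gpr149 were 10827, 207371 and 273931 bp from these CpGs, and the CpG nearest Gpr149 lay in Gm40063. Both called tiles, a count that ran from 0 to 11 when 1 library was left out and was 0 with own variances or the microglia covariate, were on chromosome 17: 1 in Lrfn2 was at 81.7% ± 4.54 (SD, n = 8) against 55.4% ± 2.37 (SD, n = 4), and 1 in Sbp at 0.883% ± 0.843 against 14.8% ± 7.96. The median level at the chromosome 17 CpGs called higher was 0% in all 8 libraries of 3 months, whereas WT libraries of 13 months were at 0% (replicate 6), 40.9% (replicate 1), 83.0% (replicate 2) and 84.6% (replicate 7), and HEM libraries of 13 months at 39.8% to 43.1% or, in replicates 3 and 8, at 80.0% and 80.5%. No gene region was called between ages in either genotype, with 571 in WT (4.63% of those tested) and 1676 in HEM (13.6%) at an unadjusted p under 0.05 (limma).

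**Figure D3:**
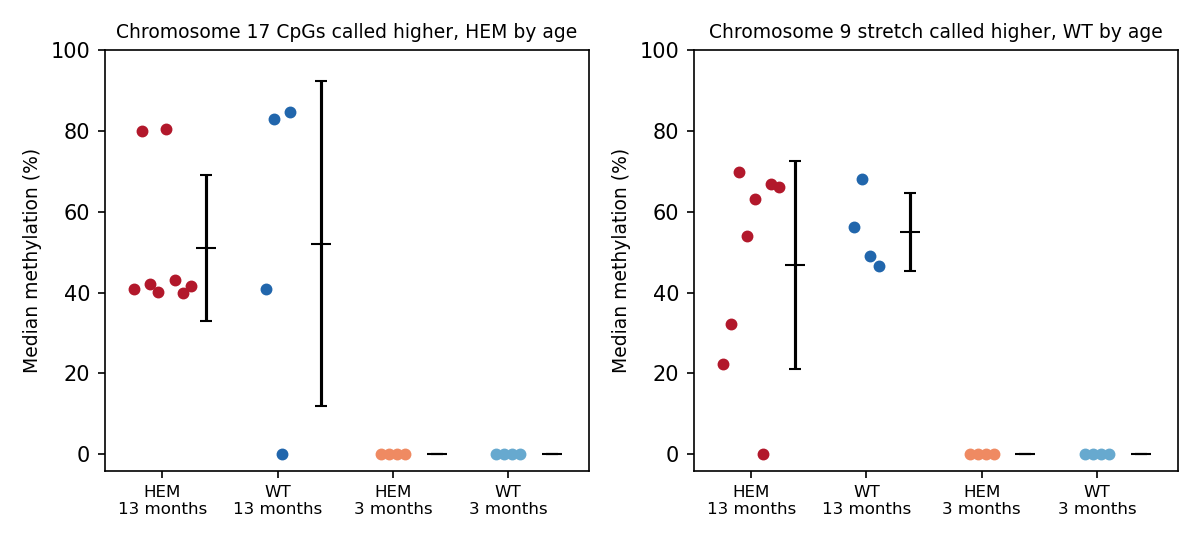
Median methylation in percent of each library (points) over the chromosome 17 CpGs called higher at 13 months in HEM, left, and over the chromosome 9 stretch called higher in WT, right, with the group mean and SD as bars. All libraries of 3 months were at 0% in both, and libraries of 13 months ran from 0% to 84.6% on chromosome 17.

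The WT and HEM age contrasts use different libraries but share the same split of age and batch. Among 421777 CpGs tested in both, 8 were called in both, in the same direction. Independent lists would share 0.0182 in the higher direction if neighbouring CpGs were independent. They are not: all 8 lay in the chromosome 9 stretch and amount to 1 locus. Of 74 WT calls tested in both, 66 had the same direction in HEM: all 55 in that stretch, but 11 of the 19 elsewhere, against 53.2% of all CpGs tested in both. Of 128 HEM calls tested in both, 122 had the same direction in WT: 95 of 97 on chromosome 17, with median differences of 50.2 points in HEM and 50.6 in WT, and 27 of 31 elsewhere, with 19.56 and 6.21 points. Among the lists, the clustered homeobox genes, 29 members of which some overlap, had a mean of 4.83% at 13 months and 3.22% at 3 months in HEM (exact permutation p = 0.0101, adjusted p = 0.182 over 18 lists). In the same contrast the microglia markers differed by -5.42 points (exact permutation p = 0.137, adjusted p = 0.440), with lower values at 13 months in 12 of 13 tested members, and higher values were found in 12 of 13 neuron and 8 of 9 oligodendrocyte lineage members. Hoxa5, a body patterning gene, was the 1 member of the 9 past the mean filter called when adjusted over the list alone, at 11.03% ± 4.76 (SD, n = 8) against 4.26% ± 1.72 (SD, n = 4; limma adjusted p = 0.00785 over the list alone and 0.230 over all genes).

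Whether the genotype difference changed with age was tested as an interaction. It was called at 1 of 446428 CpGs, at 55047326 of chromosome 14, 12941 bp from Zfhx2, and at no tile or gene region. Of tiles 4457 (6.36% of those tested) and of gene regions 613 (4.97%) had an unadjusted p under 0.05 (limma). That CpG was at 93.7% ± 3.16 (SD, n = 8) in HEM and 100% in WT at 13 months, and at 97.8% ± 0.4658 and 88.1% ± 6.54 (SD, n = 4) at 3 months (limma adjusted p = 0.0304). The count was 0 on the percent scale.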

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

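The tests of a single-CpG variant, of an effect of age or batch, of the second haplotype measure, of a chromosome 9 haplotype at Thy1 and of a wrong label were chosen after the results were seen. A rule for values far from the rest of their group marked 5 of 92 groups tested (5.43%), and chance marks about 1 in 20.

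At the 4 CpGs past the end of Thy1 the library labelled WT replicate 3 at 3 months was at 38.9%, and the other WT libraries of that age were at 83.9% to 89.5%. A varying share of microglial DNA was argued against by WT replicates 1 and 3 at 3 months, whose marker means were within 1 point and whose Thy1 levels differed by 45.0 points, and by HEM replicates 8 and 13 at 13 months, 31.9 points apart, while the other 3 such pairs were 3.25 to 10.8 points apart. A strain haplotype of chromosome 9 stays open, because the variable CpGs within 10 Mb, which put a median of 45% of libraries in the same level class (45% elsewhere), left out the 4 CpGs themselves. A wrong label and a true difference between mice cannot be told apart at 38.9%, because the files hold no other measure of the transgene. An effect of genotype also stays open. Because the transgene carries the Thy-1 promoter, Thy1 sequence of the transgene could be read at this locus in HEM mice. That was not tested, because the files give no read counts.

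Age calls clustered on chromosomes 17 (98 of 136 in HEM) and 9 (55 of 81 in WT), and age, batch and the mice used coincide. In the chromosome 9 stretch CpGs 2 to 100 bp from a called CpG differed by a median of 51.6 points, which went against a single-CpG variant. These neighbours included called CpGs, 55 of which lay in the stretch, so that median is not independent of the calls. On chromosome 17 such neighbours differed by 3.63 points, against 50.2 at the called CpGs. A strain variant on chromosome 17 is therefore a candidate explanation in this mixed-strain background. The change was not in every library of 13 months. Of called CpGs, 93.9% on chromosome 17 and 96.4% in the stretch had a 13-month library within 5 points of the 3-month mean. These were mostly WT replicate 6 and HEM replicate 10. Only 5.10% and 14.5% had 2 or more, so an effect of age or batch on the other libraries stays open in the stretch. On chromosome 17 the medians of 13-month libraries fell at 0%, at 39.8% to 43.1% or at 80.0% to 84.6%. That argues against an even effect of age or batch there, while an uneven effect stays open. A haplotype also stays open, because other variable CpGs, matching in a median of 50% of libraries on chromosome 17 (50% elsewhere) and 58.3% around the stretch (58.3% elsewhere), left out the called CpGs. On chromosome 17, 56.2% of CpGs called higher put all 4 WT libraries of 13 months, which took no part in the call, in the level class of the segment median. Of variable CpGs on other chromosomes 0.227% did. The segment median was taken over the same called CpGs, WT values included, so part of that agreement is built in. The 56.2% lay between the limits chosen for and against a haplotype, so it decides nothing. In the stretch 16.7% did, against 16.9% on other chromosomes. There those libraries made the call, and the measure is no independent check.

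The leading component of methylation across all 20 libraries held 19.3% of the variance, and a varying share of microglial DNA may lie behind it. With the CpGs of listed genes left out it followed the microglia marker mean (Pearson r = 0.896, Spearman rho = 0.878, each permutation p = 1e-05, the smallest possible, adjusted p = 6e-05 and 3e-05 over 6 lists). Without the 2 farthest libraries r was 0.838, and it was 0.883 at 13 months and 0.882 at 3 months. Leukocyte markers gave r = 0.770, neurons -0.762, oligodendrocyte lineage -0.827, endothelium -0.592 and astrocytes -0.435. The component did not differ by genotype past the test, with an exact permutation p of 0.370 at 13 months and 0.371 at 3 months. With so few libraries a part played by genotype is not excluded.

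The lysosome and autophagy list was at 19.3% in HEM replicate 7 at 3 months and at 19.91% to 19.98% in the other HEM libraries. The mitochondrial and oxidative stress list was at 15.02% in WT replicate 7 at 13 months, against 15.6% in each of the others. Imprinted genes were at 29.2% in HEM replicate 8 at 13 months, against 35.0% to 38.5%, in a library whose mean over all CpGs, 29.3%, was also the lowest of all 20 (30.5% to 32.2% in the others), and at 33.2% in WT replicate 5 at 3 months, against 36.9% to 37.5%. At the CpG near Zfhx2 on chromosome 14 the genotype difference differed between ages by -16.1 points in the limma interaction test.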

How the results depend on the processing

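The scale, offset, mean filter, covariate, variance trend, tile size and gene part alternatives, those without chromosomes 9 and 17, all for interactions and gene regions, those for Thy1, and those between ages other than leaving out libraries for tiles were chosen after seeing the data. Tile and gene region counts of HEM against WT and the count of lists that passed stayed at 0 in every alternative run, at both ages (limma and exact permutation tests). For each result below the cause was not tested, except that fewer features were tested without chromosomes 9 and 17.

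The 4 CpGs called at 13 months became 2 with each CpG's own variance, 14 with no minimum difference, 0 at 25 points and adjusted p under 0.01, 2 with both strands averaged, 0 on the percent scale, 13 with an offset of 0.5, 0 with an offset of 5 and 2 with a variance trend. The 0 CpGs at 3 months became 1 with each CpG's own variance, 8 with both strands averaged, 22 with an offset of 0.5 and 8 with no filter on the mean. Between ages in WT the 81 CpGs became 43 with own variance and 50 at 25 points and adjusted p under 0.01. They became 14 without chromosomes 9 and 17 and 38 on the percent scale. The 4 tiles became 0 without those chromosomes and 1 on the percent scale. In HEM the 136 CpGs became 79 with own variance and 77 at 25 points and adjusted p under 0.01. They became 8 without chromosomes 9 and 17 and 20 on the percent scale. The 2 tiles in HEM became 0 with own variance, at 25 points and adjusted p under 0.01, without those chromosomes and with the microglia covariate. They became 1 with an offset of 0.5 or 5 or no mean filter. The 0 gene regions in HEM became 5 with no mean filter and 1 with a variance trend. The 1 interaction CpG became 0 with own variance, on the percent scale, with an offset of 5, no mean filter, the microglia covariate or a variance trend, and the 0 interaction gene regions became 1 with that covariate.

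Leaving out 1 library gave 3 to 45 CpGs at 13 months, with 7 and 8 without HEM replicates 6 and 7, and 45, 20, 29 and 25 without WT replicates 1, 2, 6 and 7. At 3 months it gave 0 to 57, with 57 without WT replicate 1 and 1 without HEM replicate 3. Between ages it gave 63 to 181 CpGs in WT, with 125 and 181 without 13-month replicates 2 and 6, 3 to 4 tiles in WT, 114 to 195 CpGs in HEM, and 0 to 11 tiles in HEM, where the count was 0 without 13-month replicate 3, 7 or 13 or 3-month replicate 1, 3 or 7, 1 without 13-month replicate 1 or 6 or 3-month replicate 2, and 5, 11 and 4 without 13-month replicates 8, 10 and 11. HEM gene regions ranged from 0 to 5, with 5 without 13-month replicate 11 and 2 without 3-month replicate 2. Interaction CpGs ranged from 0 to 6, with 6 without WT replicate 6 and 2 without HEM replicate 10 or 11 at 13 months. It was 0 without HEM replicate 1, 3, 6 or 8 or WT replicate 1, 2 or 7 at 13 months, and without HEM replicate 1, 2 or 7 or WT replicate 1, 4 or 5 at 3 months. Interaction gene regions ranged from 0 to 1, with 1 without HEM replicate 2 at 3 months. The mean methylation difference ranged from -0.151 to 0.244 points at 13 months and turned positive without HEM replicates 3, 8 and 10 (0.0332, 0.244, 0.0713) or WT replicates 2 and 6 (0.0995, 0.0714). At 3 months it ranged from -0.174 to 0.145 and turned positive without HEM replicate 7 (0.00168) or WT replicate 4 (0.145). The Thy1 difference ranged from -15.8 to -7.48 points at 13 months and from -43.2 to -26.3 at 3 months, passing only without the library labelled WT replicate 3.

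With a replicate block on the libraries whose number both groups have, 0 CpGs were called at 13 months, and between ages in HEM 0 CpGs and 4 tiles. No other call changed. Deviations of libraries with the same number correlated at 0.103, 0.224 and 0.0480 at 13 months, where pairs with other numbers averaged -0.0129. At 3 months the values were 0.0505 and -0.111, against 0.00437. Between ages in HEM they were 0.0274, -0.152 and -0.0155, against 0.00487. The values had both signs at 3 months and between ages, which gives no sign of a pairing. At 13 months each lay above the other pairs, so a factor shared by libraries of the same number is not excluded. For the comparison of ages in WT, no paired analysis was possible because those libraries share only the number 1. Settings chosen beforehand that need read counts or coverage were not run: the chi-square test, limma on ratios of counts, other coverage minimums, coverage weights and the Thy1 coverage ratio. Narrower promoters were not run because the gene table has no strand. The depth of each library is unknown.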

Other observations

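The splits below were planned before the data were examined, except those without chromosomes 9 and 17, chosen after the results were seen. For HEM against WT at 13 months 10 of 100 splits of the libraries gave as many CpGs as the real 4, with up to 26 in another split, so chance cannot be excluded. For tiles and gene regions at 13 months the real counts were 0, so all 100 splits gave as many, and the highest others were 2 and 1. At 3 months the real counts of CpGs, tiles and gene regions were 0, so all 35 splits gave as many, and the highest others were 41, 1 and 2. Splits calling 26 CpGs where the real one called 4, or 41 where it called 0, point to a structure of the libraries or to values at the limits of the scale. In those splits 7 of the 26 and 34 of the 41 had every library of 1 group at exactly 0% or 100%. The interaction gave 1 CpG, as many as in 21 of 100 splits, with up to 4 in another, so chance cannot be excluded. For interaction tiles and gene regions the real count was 0, all 100 splits gave as many, and the highest other was 1 for each.

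Between ages in WT only the real split, 1 of 35, gave as many as 81 CpGs (highest other 36) or 4 tiles (highest other 1). That is the smallest share 35 splits can give. Chance is therefore unlikely but not excluded for these counts, and batch stays open. The WT counts rest largely on 1 stretch of chromosome 9. Without chromosomes 9 and 17, 5 of 35 splits gave as many as the real 14 CpGs (highest other 36), so these splits do not make chance unlikely elsewhere. In HEM only the real split, 1 of 100 drawn, gave as many as 136 CpGs (highest other 40). Chance is unlikely but not excluded for that count, of which 98 lay on chromosome 17. Without chromosomes 9 and 17, 4 of 100 gave as many as the real 8, a share under the limit used. Another split called 87, which points to a structure of the libraries other than age. Since this test was also chosen after the results were seen, chance is not taken as excluded for the 8 CpGs. For tiles in HEM 4 of 100 splits gave as many as the real 2, a share under the limit set beforehand. Another split called 2540, which points to a structure of the libraries other than age. Chance is therefore not taken as excluded for the 2 tiles. For gene regions the real counts were 0, so all 35 splits in WT and all 100 in HEM gave as many, with highest others of 5 and 71.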
